A study of Danio rerio with 3 samples.

How the data were processed

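RNA from pooled whole zebrafish embryos was compared on 3 two-colour Agilent oligonucleotide arrays, 1 per biological replicate. Embryos were raised for 24 h in medium with 75 uM 5-aza-2'-deoxycytidine (5azadC), a cytidine analogue that traps DNA methyltransferases once built into DNA, or in plain medium. Per the labels, the Cy5 (red) channel of each array held RNA of treated embryos and the Cy3 (green) channel RNA of untreated embryos. The dyes were not swapped on any array, so a dye preference of a probe cannot be told apart from a treatment effect.

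The deposited scanner files gave, per the file headers, spot intensity in each channel from Agilent Feature Extraction version 9.5.3.1, with mean spot intensity and local background intensity before correction, and processed intensity after background subtraction, spatial detrending and dye normalization. The same files held the scanner software's log10 ratio of red over green, per the file headers. The series matrix held at most 1 value per probe and array, which the authors deposited with scale and centring unstated; 67, 3826 and 3470 of 21495 probes were blank on replicates 1, 2 and 3. Against the scanner log ratio, the deposited values gave Pearson's r across probes of 0.996, 0.97 and 0.973 on replicates 1, 2 and 3. Since r was positive, they were read as treated over untreated. Pearson's r is the same for any log base, so it cannot tell which base the authors used. The series matrix values were taken, here and below, as log2 ratios that the authors had normalized before they deposited them, which is an assumption. Their medians were 0.08, -0.03 and 0.02. How they were normalized remains unknown. The authors also deposited lists of probes with a normalized ratio past a fold limit, made in GeneSpring per the deposited notes. All 42990 gene spots and 1417 control spots of each array were read.

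From the mean and background intensities, background was corrected by normexp with offset 50, and each array was normalized by loess with control spots at weight 0. Spots flagged as non-uniform or population outliers were left out (80, 13 and 18 gene spots on replicates 1, 2 and 3), and the 2 spots of a probe were averaged. Of 21495 probes, 15859 were kept because they were well above background in at least 1 channel on all 3 arrays, and 14602 were so in both channels. No gene spot was saturated. Probes were named through reference tables of assembly GRCz12tu where their accession, symbol or synonym matched (10303 probes), and otherwise kept the name in the file (11192 probes). Probe positions are those of the scanner files, on zebrafish build danRer2.

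The mean log2 ratio of each probe was tested against 0 with limma version 3.58.1 in R version 4.3.3 (lmFit with an intercept, then eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. Each array was 1 replicate, since it holds 1 treated and 1 untreated pool. Where a gene had several probes, the brightest was used, which left 13077 genes. Before the data were examined, 26 gene lists were fixed for embryonic tissues, DNA methylation, stress and growth. They were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. A gene belonged to a list when its updated symbol or its name in the file matched. Limma's p was also adjusted over the members of each list alone, with no adjustment across the 26 lists. This is a looser test than over all genes, since 2519 of the 13077 genes had an unadjusted p under 0.05.

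The rule for named genes, fixed before the data were examined, took the 8 highest and 8 lowest genes past the threshold with one sign on all 3 arrays, the member of each list with the smallest p (up to 4 where members passed), and dnmt1. The main test passed no gene, so the first part named none. It was then applied to the limma test with an intensity trend and robust variance, an alternative planned beforehand. That step, and the further list members given as examples, were chosen after the values were seen. One result on a single gene is withheld for evaluation and left out of the text and figure. Of 2154 genes with several kept probes, 40 had probes that differed in sign and by over 1 on the log2 scale.

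Alternatives were no background subtraction, offset 16, processed intensities, median centring, scale normalization, the series matrix, no filter or a filter on both channels, trend and robust variance, array weights, channels compared without the array as a block, each replicate left out, and other list tests. Lists matched on file names alone, lists without probes resembling ribosomal RNA, and the trend and robust test without replicate 1 were added after the data were seen. Leaving out saturated probes was also planned but changes nothing here. The procedure was tested on simulated data for the 15859 probes with the spread of the real ones. The main test recovered 0% of probes changed by 0.58 on the log2 scale, 26% of those changed by 1, 66% by 2 and 84% by 3. Each size had 50 probes in a single run with independent noise and no dye bias or array effects, so recovery on real arrays may differ. In the real data, the mean ratio was at least 2-fold higher for 96 probes and lower for 94, and none passed. On arrays, the number of replicates limits the precision.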

Results

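Gene expression was measured in 24 h zebrafish embryos raised with 75 uM 5azadC and in untreated embryos, to find which transcripts differ after exposure to an inhibitor of DNA methylation. There were 3 treated and 3 untreated pools, paired on 3 arrays. Values below are log2 ratios of treated over untreated, as mean ± SD over the 3 arrays. Replicate 1 differed from the other arrays in signal. Its median spot intensity was 447 in the green and 861 in the red channel, against 169 and 192 on replicate 2 and 181 and 154 on replicate 3. The red channel was well above background at 98.7% of gene spots on replicate 1, 78.0% on replicate 2 and 76.0% on replicate 3. The slope of observed against expected spike-in ratios was 0.66 on replicate 1, outside the range set in the file header, and 0.89 and 0.88 on replicates 2 and 3.

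Lens, skeletal muscle and neural transcripts were lower in treated embryos, and ribosomal protein transcripts were higher, as gene lists tested against all other genes at a preset correlation. With an estimated correlation none of these lists passed (adjusted p of 0.785 to 0.835). No single probe passed limma's adjusted p of 0.05 across the 15859 tested, and the smallest adjusted p was 0.123. At an unadjusted p under 0.05 there were 3162 probes, of which 1243 were higher and 1919 lower, where 793 are expected by chance. That count was 522 with median centring in place of loess, 1549 without the array as a block, 1634 and 1891 without replicates 2 and 3, 4750 without replicate 1 and 5768 with array weights. Without replicate 1, more were higher (2490) than lower (2260), the reverse of the main count. With an intensity trend and robust variance, limma called 751 probes (332 higher, 419 lower), and 133 of them differed at least 2-fold. Without replicate 1, the main test called 1159 probes (613 higher, 546 lower), and 498 probes were called by both of these alternatives. Of the 15859 kept probes, 50.2% had one sign on the 3 arrays, where chance gives 25%, and 19.5% did so with median centring. With dyes not swapped, a dye preference would also repeat its sign on every array. Neither the 25% nor the 793 allows for that. Across probes, which are not independent replicates, Pearson's r was 0.50 between replicates 1 and 2, 0.34 between 1 and 3, and 0.64 between 2 and 3. Spearman's rho was 0.39, 0.30 and 0.67.

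Genes of the eye lens had lower transcript levels, led by structural crystallins and a membrane channel of lens fibres. Of 11 measured members of the lens list, 7 passed limma's threshold adjusted over the list alone, 6 lower and 1 higher, and none did over all genes. The crystallin gene cryba2a fell by 2.27 ± 0.56 (SD, n = 3), cryba1b fell by 2.37 ± 1.12, and lim2.4, which encodes a lens fibre membrane protein, fell by 1.33 ± 0.26. The water channel gene mipa fell by 1.98 ± 0.41, with a probe at chromosome 23, 32547153 to 32547212, and its second probe gave -1.92. The crystallin gene crygn1 rose by 0.53 ± 0.18, while cryaa was at 0.10 ± 0.48, with other probes at -0.22 and 0.17. Outside the list, crygm2d18, a further crystallin gene, was at -2.04 ± 0.52 with an adjusted p of 0.00499 in limma's test with trend and robust variance. The list's median was -0.62 (camera adjusted p = 0.00453). Its estimated correlation was 0.576, far above the preset 0.01, and with that estimate camera's adjusted p was 0.835. Camera with a variance trend gave an adjusted p of 0.363, and matching on the names in the files alone gave 0.556; the median was -0.099 without a filter, and -1.37 with processed intensities, -1.28 with the filter on both channels and -1.22 with the series matrix.

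Transcripts of the skeletal muscle list were lower. Of 39 measured muscle genes, 33 had a ratio below 0, and 16 passed limma's threshold adjusted over the list alone, 14 lower and 2 higher, against 0 over all genes. The fast myosin heavy chain gene myhz2 fell by 1.43 ± 0.41 (SD, n = 3), the troponin gene tnnt3b by 1.21 ± 0.31, the creatine kinase gene ckmb by 1.15 ± 0.34 and the alpha-actinin gene actn3b by 0.91 ± 0.07. The other probes of tnnt3b ranged from -1.49 to 0.27, and those of ckmb were at 0.03 and -0.21. The transcription factor gene mef2d went the other way and rose by 1.097 ± 0.31, with its second probe at 0.31. The median of the list was -0.40 (camera adjusted p = 7.41e-06), with medians of -0.27, -0.47 and -0.51 on replicates 1, 2 and 3. The adjusted p = 0.785 with an estimated correlation, and the median was -0.245 with median centring. Among genes outside the list, smpx, a small muscle protein gene, was at -1.53 ± 0.85, with an adjusted p of 0.0352 in limma's test with trend and robust variance. The heart list did not pass (adjusted p = 0.665). Its median was -0.10 and its mean 0.08 over 17 genes, and the median was -0.000704, 0.00504 and 0.0322 without replicates 1, 2 and 3. Its member with the smallest p was tbx2b at -0.45 ± 0.08.

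Genes of neurons and neural progenitors were lower as lists. Among 33 neuron genes, 27 lay below 0, and 7 passed the threshold adjusted over the list alone, 6 lower and 1 higher. The proneural genes neurod4 and ascl1a fell by 0.98 ± 0.32 and 0.75 ± 0.24 (SD, n = 3), the RNA-binding protein gene nova2 fell by 0.87 ± 0.31, and isl2b, a LIM homeobox gene, rose by 0.56 ± 0.12. The list's median was -0.29 (camera adjusted p = 0.000344), and its adjusted p = 0.785 with an estimated correlation. Of 52 progenitor and brain patterning genes, 37 lay below 0, and 8 passed adjusted over the list alone, 6 lower and 2 higher. The retinal gene rx2 fell by 1.02 ± 0.41, and sox3, a progenitor gene, fell by 0.91 ± 0.33, whereas mafba, a hindbrain patterning gene, rose by 0.87 ± 0.45. The median of this list was -0.24 (camera adjusted p = 0.00453), and its adjusted p = 0.785 with an estimated correlation; the median was -0.16 without replicate 1, -0.159 with array weights and -0.148 with median centring. Further genes with low ratios were foxn4, a retinal progenitor gene, at -1.36 ± 0.25 and prox1a, a homeobox gene of lens, liver and lymphatic cells, at -1.55 ± 0.78. Their adjusted p values in limma's test with trend and robust variance were 0.0166 and 0.0299.

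Transcripts for cytosolic ribosomal proteins were higher. Of 65 measured genes, 58 lay above 0, and 32 passed the threshold adjusted over the list alone, 31 higher and 1 lower, against 0 over all genes. The gene rpl35a rose by 1.05 ± 0.23 (SD, n = 3), rps12 by 0.80 ± 0.20, rpl38 by 1.42 ± 0.59 and rps28 by 0.97 ± 0.35. The list's median was 0.41 (camera adjusted p = 6.89e-15), and 0.742 with median centring. Its estimated correlation was 0.563, far above the preset 0.01, and with that estimate camera's adjusted p was 0.785. Apart from the lens list, the other lists past the threshold had estimates from 0.00147 to 0.0973. On replicates 1, 2 and 3 the medians were 0.62, 0.46 and 0.20. Probes for ribosomal RNA were also higher, most so on replicates 1 and 2. Over 20 such probes, the median ratio was 4.05 and 4.51 on replicates 1 and 2 and 0.972 on replicate 3. Relative to the upper quartile of each channel, their median treated log2 level was 3.73, 3.62 and 4.1 on replicates 1, 2 and 3. The untreated level was -0.112, -0.583 and 3.73, so the ratio varied mainly with the untreated samples. Without probes resembling ribosomal RNA, the ribosomal protein list kept a median of 0.41 (camera adjusted p = 4.48e-15). No other link between ribosomal RNA and the ribosomal protein transcripts was tested. Among single genes, limma's test with trend and robust variance called rpl29 at 1.33 ± 0.33 and rpl28 at 1.304 ± 0.80, with adjusted p of 0.00499 and 0.0274. The same test called cox7c, a respiratory chain subunit gene, at 1.33 ± 0.29 (adjusted p = 0.00499), cdh2, the N-cadherin gene, at 1.29 ± 0.34 (adjusted p = 0.00642) and Smarcc1, a chromatin remodelling gene, at 1.48 ± 0.08 (adjusted p = 0.00499). It also called uox, the urate oxidase gene, at 1.77 ± 0.38 (adjusted p = 0.00499) and igf1ra, a growth factor receptor gene, at 1.62 ± 0.53 (adjusted p = 0.0146). Other probes of uox ranged from 0.13 to 1.76, and the second igf1ra probe was at 0.12.

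**Figure D1:**
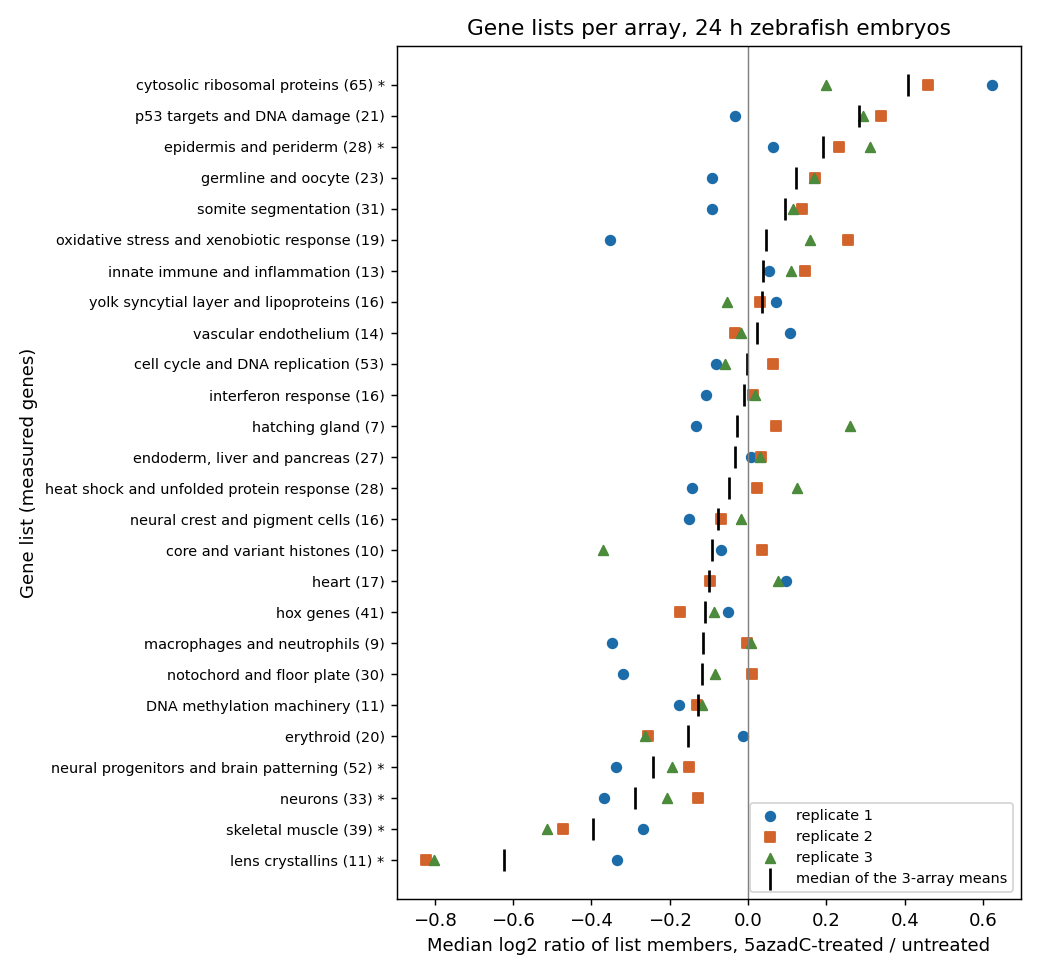
Median log2 ratio (treated over untreated, horizontal axis) of each of 26 gene lists (vertical axis, measured genes in brackets) on each array, with a black bar for the median of 3-array means; an asterisk marks a camera adjusted p under 0.05 at the preset correlation. Ribosomal proteins lie highest at 0.41 and the lens list lowest at -0.62.

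Epidermal genes moved in both directions, with more members higher. Of 28 measured genes, 20 lay above 0, and 7 passed the threshold adjusted over the list alone, 4 higher and 3 lower. The annexin gene anxa1b rose by 0.94 ± 0.11 (SD, n = 3) and icn, a calcium-binding protein gene, by 0.95 ± 0.48, while the ionocyte genes atp1b1b, a sodium pump subunit, and ca2, a carbonic anhydrase, fell by 0.85 ± 0.06 and 0.46 ± 0.10. The list's median was 0.19 (camera adjusted p = 0.0225), and its adjusted p = 0.785 with an estimated correlation. Camera's adjusted p was 0.173 without replicate 3, 0.092 with processed intensities, 0.114 with the series matrix and 0.0626 with the mean over all probes of a gene, and the median was 0.318 with median centring. The hatching gland list of 7 genes did not pass (median -0.03, mean 0.14, adjusted p = 0.64), and its median was 0.166 without replicate 1, -0.0728 without replicate 2, -0.172 without replicate 3 and 0.104 with median centring, but the hatching enzyme genes he1.2 and he1.3 rose by 0.97 ± 0.06 and 0.59 ± 0.28 in the test adjusted over the list alone, and the second he1.3 probe was at 0.08.

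Genes of the DNA methylation machinery did not pass as a list or singly in the main test, though fry's mixed test, for changes in either direction, gave the list an adjusted p of 0.000155 and passed 21 of the 26 lists. The maintenance methyltransferase gene dnmt1, with a probe at chromosome 9, 10777980 to 10778039, was at -0.15 ± 0.12 (SD, n = 3; limma adjusted p = 0.488). With median centring in place of loess its ratio turned to 0.01. The chromatin remodeller gene hells was at 1.07 ± 0.55, with an adjusted p of 0.0282 without replicate 1 and 0.0532 with trend and robust variance. The median of 11 genes was -0.13 (adjusted p = 0.665), and the mean was 0.01. The germline list had a median of 0.12 over 23 genes (adjusted p = 0.108), of which 16 lay above 0. Its member with the smallest p was h1-10, a linker histone gene, at -0.67 ± 0.46. That gene entered by its name in the file, h1fx, listed as an alias of h1m, and h1m was at 0.30 ± 0.22. The germline list's adjusted p was 0.835 with an estimated correlation and 0.389 without replicate 2 (median 0.0557). It passed without replicate 1 (0.0131), without background subtraction (0.0298), with scale normalization (0.0288), with array weights (0.0173), and with processed intensities (median 0.389, adjusted p = 0.00713) and the series matrix (0.369, 0.00581).

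Transcripts of the p53 and DNA damage list lay above 0 for 14 of 21 genes, with a median of 0.28, and did not pass (camera adjusted p = 0.0759). The cyclin gene ccng1 was at 0.89 ± 0.62 (SD, n = 3), with the lowest value on replicate 1 (0.27). Its limma adjusted p was 0.173, and 0.0456 with trend and robust variance and 0.0338 without replicate 1. None of the 21 passed adjusted over the list alone. The median was -0.03 on replicate 1; without that array it was 0.52 (camera adjusted p = 0.00512), and without replicate 3 it was 0.132 (0.173). The adjusted p was 0.835 with an estimated correlation, and the list passed with median centring (0.0101), the filter on both channels (0.0463), array weights (0.0143), no replicate block (0.0129) and the mean over all probes (0.0343). Erythroid genes had a median of -0.15 over 20 genes (adjusted p = 0.0915), and epb41b, a membrane skeleton gene, fell by 0.70 ± 0.12 in the test adjusted over the list alone. The erythroid adjusted p was 0.785 with an estimated correlation, 0.0137 without replicate 1 (median -0.267), 0.0292 without a filter, 0.0253 with array weights (median -0.251) and 0.0291 without the replicate block, and the median was 0.00424 with median centring.

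Among the embryonic tissue lists that did not pass, the notochord list had a median of -0.12 (adjusted p = 0.108), and its collagen gene col9a3 fell by 1.503 ± 0.36 (SD, n = 3) in the test adjusted over the list alone. The notochord list passed without replicate 2 (adjusted p = 0.0342) and without a filter (0.0273), but its median was -0.0439 without replicate 1, -0.026 with array weights, -0.0582 with median centring, -0.2 without replicate 3 and -0.204 with the series matrix, and its adjusted p was 0.835 with an estimated correlation. The somite segmentation list had a median of 0.09 and a mean of -0.05 (adjusted p = 0.719). Within it the Notch pathway genes her4.5 (her4 in the file) and lfng fell by 1.34 ± 0.51 and 0.81 ± 0.24 adjusted over the list alone, and cyp26a1, which degrades retinoic acid, rose by 0.46 ± 0.03. In the neural crest list (median -0.08, adjusted p = 0.27; median -0.0399, -0.0496 and -0.144 without replicates 1, 2 and 3), paics, a purine synthesis gene, fell by 1.16 ± 0.17, with its other probes at -1.26 and -1.27. The hox list had a median of -0.11 (adjusted p = 0.168), with hoxb9a at -1.05 ± 0.33. It passed without replicate 1 (0.00458), without a filter (0.0292) and with array weights (0.00767), but its adjusted p was 0.785 with an estimated correlation and 0.687 without replicate 2 (median -0.0596). The endoderm list (median -0.03, adjusted p = 0.719; medians from -0.0454 to 0.0132 with a replicate left out and 0.0859 with median centring) had prss1, the trypsin gene, at 0.57 ± 0.09. In the yolk and lipoprotein list (median 0.03, adjusted p = 0.889), the selenoprotein gene selenop fell by 0.89 ± 0.19 adjusted over the list alone. The vascular list (median 0.02, adjusted p = 0.889) had robo4, a guidance receptor gene, at -0.53 ± 0.14.

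The stress, immune, cell cycle and histone lists did not pass. The heat shock list had a median of -0.05 (adjusted p = 0.813), and the mitochondrial chaperonin genes hspe1 and hspd1 rose by 0.70 ± 0.09 and 0.54 ± 0.06 (SD, n = 3) adjusted over the list alone, while canx, an endoplasmic reticulum chaperone gene, fell by 0.58 ± 0.11 on its brightest probe and was at 0.589 on its second. The oxidative stress list was at 0.04 (adjusted p = 0.497), with the catalase gene cat at -0.61 ± 0.13, and without replicate 1 its adjusted p was 0.0492 (median 0.17), but its median turned to -0.0597 without replicate 2 and -0.186 without replicate 3. The cell cycle list was at -0.0018 (adjusted p = 0.916), with rpa3, a replication protein gene, at 0.82 ± 0.18. In the histone list (median -0.09, adjusted p = 0.445), 6 of 10 genes passed adjusted over the list alone, 2 higher and 4 lower. The H3.3 genes h3f3d and h3f3c fell by 0.60 ± 0.06 and 0.50 ± 0.12, the core histone gene hist2h2l rose by 0.40 ± 0.15, and h3f3a, a further H3.3 gene, was at -0.08 ± 0.35 with other probes at 0.113 and 0.747. The median was -0.168, -0.155 and 0.0253 without replicates 1, 2 and 3, and 0.064 with median centring. The interferon list had a median of -0.01 (adjusted p = 0.889), and 0.0534 with median centring, with mxc at 0.38 ± 0.08. The innate immune list was at 0.04 (adjusted p = 0.64), 0.108 without replicate 1 and 0.185 with median centring, with the complement gene cfb at -0.45 ± 0.07. The macrophage and neutrophil list was at -0.11 (adjusted p = 0.445), and at -0.0336, -0.276 and -0.167 without replicates 1, 2 and 3, with coro1a, an actin-binding protein gene, at -0.48 ± 0.20. Camera's direction, the median and the mean did not share a sign in 9 of the 26 lists, none of them past the threshold.

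**Figure D2:**
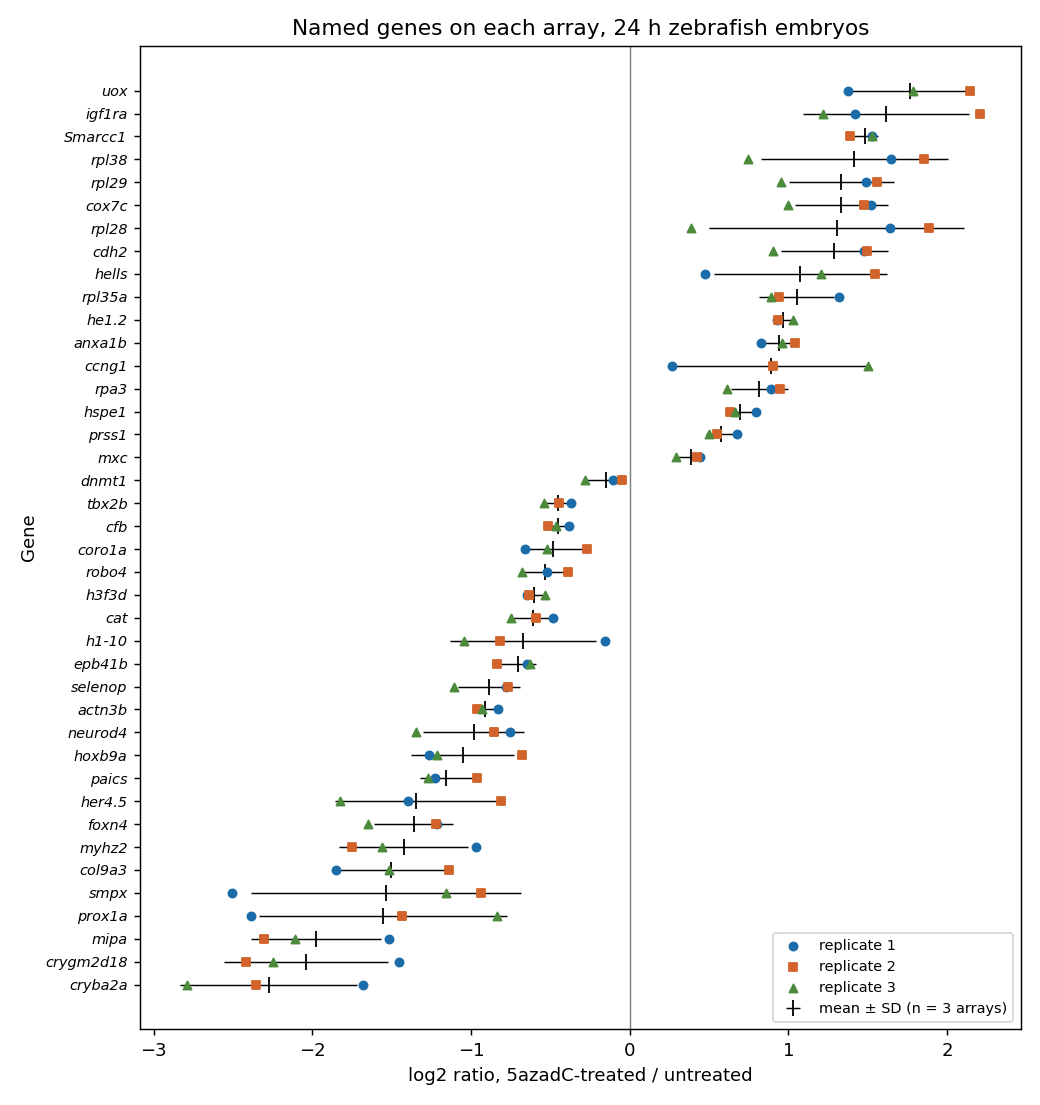
Log2 ratio (treated over untreated, horizontal axis) of the genes picked by the naming rule (vertical axis) on each array, with a black tick and line for mean ± SD over 3 arrays. The range runs from cryba2a at -2.27 to uox at 1.77, and dnmt1 lies at -0.15.

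The authors' deposited lists hold 472 probes past 2-fold and 2347 past 1.5-fold in at least 2 of 3 arrays. Of the 472, 467 were kept here, and the mean ratio had the same sign for all 467. At an unadjusted p under 0.05 there were 398 of them, more than among other probes by Fisher's exact test (odds ratio 26.3, p = 7.47e-211). None passed limma's adjusted threshold, and 184 did so with trend and robust variance. The lists come from the same arrays, so this overlap is not independent evidence.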

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

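The tests of the ribosomal RNA pattern and of slower development, and the correlations without probes resembling ribosomal RNA, were chosen only after the result was seen.

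Dark corner spots, which carry no gene probe and enter no comparison, had a median red intensity of 167.7 on replicate 1, above the negative controls of the same array (median 125.6), against 64.38 and 62.6 on replicates 2 and 3. Log2 ratios of replicate 1 also followed the other arrays less closely among dim probes. A higher unspecific floor on replicate 1 is a candidate explanation. Among the brightest 25% of probes, the correlation of replicates 2 and 3 minus that of replicate 1 with their mean was -0.214. A correlation with a mean of 2 arrays is not like that of a single pair. Pair by pair, these bright probes gave 0.885 for replicates 1 and 2, 0.581 for 1 and 3, and 0.616 for 2 and 3. Among the dimmest 25%, replicate 1 correlated with that mean at 0.296, where under 0.2 had been set for this explanation, so it stays open. Without probes resembling ribosomal RNA, the brightest 25% gave 0.765 for replicate 1 with the mean and 0.707 for replicates 2 and 3.

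The 20 ribosomal RNA probes kept had median ratios of 4.05, 4.51 and 0.972 on replicates 1, 2 and 3. A treatment effect of one size is argued against, since replicates 1 and 2 averaged 3.31 (log2) above replicate 3. The untreated level of replicate 3 lay 4.08 (log2) above the mean of replicates 1 and 2, while treated levels spanned 0.485, as unequal labelling of ribosomal RNA in single untreated samples would give. Some probes named for other genes may carry this signal, since the other probes of vangl2 and gldc, 2 in number, had a median ratio of 0.0052. No biological difference between the untreated pools was tested.

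Lens, muscle and neuron lists were lower at the preset correlation, and none passed with an estimated one (adjusted p of 0.785 to 0.835). Relative to 10000 lists matched on brightness and gene span, the percentile of the list median was 0 for the lens, 0 for muscle and 0 for neurons. Longer genes had lower ratios (Spearman's rho -0.141 across 6190 genes), and the median span over all genes was 14780. The lens (7061) and muscle (12990) lists had shorter spans, so such a trend would not lower them and their percentiles could hardly test it. The neuron list (16060) was only slightly longer, so a span trend could lower it little and its percentile was a weak test too. Lists matched to it had a median of -0.0314, against -0.288 for neurons. Genes in a list are not independent of each other, so a percentile describes these arrays. Slower development of treated embryos might lower late-stage genes, but the somite segmentation list, active earlier, had a camera p of 0.555 and a median of 0.09, so this stays open. Dye preference cannot be separated from treatment here, and a direct effect of the drug was not tested.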

How the results depend on the processing

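The trend and robust test without replicate 1, lists matched on file names alone and lists without probes resembling ribosomal RNA were chosen after seeing the data. The count of 0 probes past the threshold held under every change of background, normalization and filter and without the array as a replicate block, where 8 lists passed. It became 751 with trend and robust variance, 2929 with array weights (0.26, 3.19 and 1.23 for replicates 1, 2 and 3), 0 to 1159 with each replicate left out (0 without replicate 2, 15 without replicate 3), and 2109 with trend and robust variance without replicate 1. At least 2-fold, these counts were 133, 210, 0 to 177, and 176. Calls arose with a changed variance model, with less or no weight on replicate 1, and without replicate 3, and why was not tested. All 15 calls without replicate 3 were higher, at least 2-fold. Ribosomal RNA probes were high on replicates 1 and 2 (median ratios of 4.05 and 4.51). Whether the 15 were such probes was not tested. The 6 lists became 10 with array weights, 5 to 11 with a replicate left out, 0 with an estimated correlation and 0 with fry; other settings gave 5 to 9. Fry's mixed test, which takes changes in either direction within a list and does not set it against other genes, passed 21 of 26. The share of probes with one sign fell from 50.2% to 19.5% with median centring, and the cause was not tested. The overlap of 398 probes with the authors' 2-fold list became 401 and 432.

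Camera's direction turned only in lists that did not pass, and the sign of dnmt1 turned to 0.0114 with median centring. The list medians in those settings were as follows. The DNA methylation list gave 0.0114 with median centring. The vascular list gave 0.0237 with processed intensities, 0.0667 with median centring, 0.018 with scale normalization, 0.0241 without a filter, -0.0197 with array weights, 0.0103 over all probes of a gene and -0.0685 with file names. The heart list gave -0.079 and the cell cycle list 0.0182 with array weights, and the latter -0.0194 with the filter on both channels. The yolk list gave 0.0343 over all probes and with fry, and -0.144 with file names. The heat shock list gave -0.049 without a filter. With a replicate left out, medians ran from -0.0299 to 0.0178 for the vascular list, 0.0255 to 0.109 for somites, -0.044 to 0.0577 for yolk, -0.0903 to 0.00543 for the cell cycle and -0.0873 to 0.0843 for heat shock. Every list that did not pass had a median that moved by over 1.5 times in some setting. So did the lists that passed, apart from neurons. With median centring, ribosomal proteins gave 0.742, muscle -0.245, progenitors -0.148 and epidermis 0.318. The lens list gave -0.099 without a filter and -1.37 with processed intensities. The cause was not tested.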

Other observations

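The test of transposable elements was chosen only after the result was seen, because the first search of probe descriptions also took up names of other kinds. The search for respiratory chain and ATP synthase genes was fixed before its values were seen.

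Nuclear-encoded small subunits of the respiratory chain and of ATP synthase were higher on balance. Of 34 genes, 31 lay above 0, with cox7c at 1.33, atp5mc1 at 1.11 and atp5mc3b at 0.87, and cox6b1 at -0.51. The median was 0.59, 0.54 and 0.32 on replicates 1, 2 and 3. As a hypothesis, the higher ribosomal protein transcripts may be part of a rise of short abundant transcripts at large. Transcript length was not measured, and these 34 genes form a single functional group, so they cannot speak for all such transcripts. The median of these 34 genes was 0.437, near the ribosomal protein median of 0.41, with a camera p of 2.44e-13 and p = 0.141 with an estimated correlation. A dye preference for such transcripts stays open, since no array had swapped dyes. Unequal labelling of single untreated samples, raised above for ribosomal RNA, was not tested for these transcripts and stays open too. On replicates 1, 2 and 3, ribosomal protein medians were 0.62, 0.46 and 0.20 and ribosomal RNA medians 4.05, 4.51 and 0.972. Each of these sets was lowest on replicate 3, as were the respiratory genes.

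Loss of methylation might release transposable elements. Among 11 probes described as such, the median log2 ratio was 0.0712, 7 lay above 0, and the camera p was 0.907, so no shift was detected with these few probes. The wider first search gave 25 probes and a median of 0.03. One of the 11, described as an envelope protein, was at -1.50.

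The number of probes at an unadjusted p under 0.05 was 3162 as measured. Turning the sign of 1 array at a time gave at most 638, so 1 of the 4 sign patterns reached the real number. With 4 patterns no share under 0.05 can be had.

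The names of the authors' deposited lists of single arrays and the replicate labels used here did not match. Whether the lists or the arrays carry the wrong label is open, and the replicate numbers given for single arrays follow the array labels. The list named for replicate 3 held 1572 probes, all past 2-fold on replicate 1 in the series matrix. The one named for replicate 1 held 578 probes, all past 2-fold on replicate 2, and the one named for replicate 2 held 1117, all past it on replicate 3.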
